A study of Mus musculus with 14 samples.

How the data were processed

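RNA was measured in whole heads of mouse embryos at E12.5, on the C57BL/6J background, in 14 libraries. Per the labels, 5 libraries came from Zcchc8+/+ heads (WT), 3 from Zcchc8+/- heads (HET) and 6 from Zcchc8-/- heads (KO). Heads were kept in RNAlater and homogenized with beads, and stranded libraries were made from polyadenylated RNA selected out of total RNA. The series' design text speaks of embryos but does not tie each library to its own embryo, so p-values may measure only the spread between these samples.

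The submitters' processing notes name bcl2fastq, FastQC 0.10.0, TopHat2 2.1.0, Partek, Cuffdiff and the genome build mm10, without saying what each was used for. The strand setting, the gene models and the filters are not given in the sources used here. The authors deposited 1 table per library with FPKM values (fragments per kilobase of transcript and per total fragments) from Cuffdiff for 67811 loci. The authors also deposited a matrix of log2 FPKM values whose columns share the same quartiles, so it had been quantile normalized, and which is blank wherever the FPKM is 0. A value of 0 means that no fragment was assigned or no estimate was made. The files hold no read counts and no whole reads could be recovered, so total depth is unknown. Relative depth was read from the lowest FPKM steps over loci under 0.3 FPKM, in log2 bins of 0.02, and had medians of 1.15 in WT, 1.30 in HET and 1.31 in KO libraries, relative to WT1.

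A locus is the authors' unit and carries a coordinate range that can span several genes. Of the loci, 14314 had no gene name and are called unannotated, and 2593 had several names, which are given together. Fragments of overlapping or antisense genes, and of near-identical copies such as histone, small nuclear RNA and crystallin genes, cannot be told apart within these values. Coordinates are those of the files, in mm10, written from 1. Exon numbers, gene types and distances to gene starts came from the GENCODE M21 annotation of the same build, to which 85.8% of the tested loci with a single name were matched.

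The values were analysed as log2(FPKM + 0.1), which shrinks fold changes of loci that are low in every library of a group. Log2 differences are between group means of log2 values. Where 1 library stands far above others at 0, they can exceed the log2 ratio of the mean FPKM values. Loci with an FPKM of at least 0.5 in at least 3 libraries were kept, which left 18217. Differences between genotypes were tested with limma-trend (limma 3.58.1 in R 4.3.3, with robust moderation) in 1 fit of all 14 libraries with a mean per genotype and no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all tested loci with a threshold of 0.05. Single values per library were compared by two-sided exact permutation tests with scipy 1.17.1, on Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6. Figures were drawn with matplotlib 3.10.9. On simulated data with known changes, the fit recovered 65.7% of changes of 0.5 log2 and 90.9% of changes of 2 log2 in KO against WT over 18217 loci, with 8 false calls. In HET against WT it recovered 43.3% of changes of 0.5 log2, 64.2% of 1 log2 and 92.4% of 2 log2, with 7 false calls. The simulation drew independent normal noise around the WT mean of each locus and changed few loci. It held no values at 0, no correlation between loci and no library effects, so error rates in the real data may differ.

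Before the data were examined, 32 gene lists were fixed, which cover RNA processing, stress responses, cell types of the head, genes near Zcchc8 and sex-linked genes. They were tested against all other tested loci with camera at a preset correlation between genes of 0.01, adjusted over the lists, and beside it with an estimated correlation and with fry. Calls within a list were counted over all tested loci and again adjusted over the list alone. The genes named in the text were also set by a rule fixed then. They are Zcchc8, the 12 largest rises and 12 largest falls in KO against WT among called loci with a mean FPKM of at least 1 in the higher group and every KO library on the same side of the WT mean, the 5 largest each way in the other comparisons, and the 3 members of each list with the smallest p, or 4 in lists past the threshold. Not every gene that the rule takes is reported here. The word gene in that rule was read as a locus with a gene name after the data had been seen.

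The alternatives were pseudocounts of 0.5 and 1, no filter and a stricter filter, other scalings, the replicate number as a block, fits of only the compared groups, library weights, sex as a covariate and leaving out each library in turn. Sex was read from Xist and Y-linked RNA, and the males were WT1, WT3, WT4, HET3, KO2 and KO3. Chosen after seeing the data were the authors' matrix as input, loci with a single name, female libraries alone, loci spanning at least 300 bases and camera among named loci.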

Results

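Polyadenylated RNA was profiled in whole E12.5 mouse heads, brain included, of the genotypes Zcchc8+/+, Zcchc8+/- and Zcchc8-/-. ZCCHC8 is the scaffold of the nuclear exosome targeting complex, which hands short and unstable nuclear transcripts to the RNA exosome for decay. The data comprised 5 WT, 3 HET and 6 KO libraries with FPKM values for 67811 loci, of which 18217 were tested. Total depth is unknown, and relative depth ranged from 1.0 to 1.49 of that of WT1.

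Zcchc8 RNA followed the genotypes. At the Zcchc8 locus (chromosome 5, 123698294 to 123721100, mm10), FPKM was 39.7 ± 2.32 (SD, n = 5) in WT, 25.7 ± 1.64 (SD, n = 3) in HET and 15.5 ± 3.91 (SD, n = 6) in KO. KO heads were at 39.1% of the WT level and HET heads at 64.8%. The KO libraries ranged from 9.27 to 20.6 FPKM, below every WT and HET library. The log2 difference from WT was -1.39 (SE 0.15, limma-trend adjusted p = 2.1e-06) in KO, and a two-sided exact permutation test of the FPKM values gave p = 0.00216. In HET it was -0.62 (SE 0.18) with a limma-trend adjusted p of 1, while the exact permutation test gave p = 0.0179, the smallest that 5 against 3 libraries allow. Which part of the gene is altered is not given in the sources used here.

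**Figure D1:**
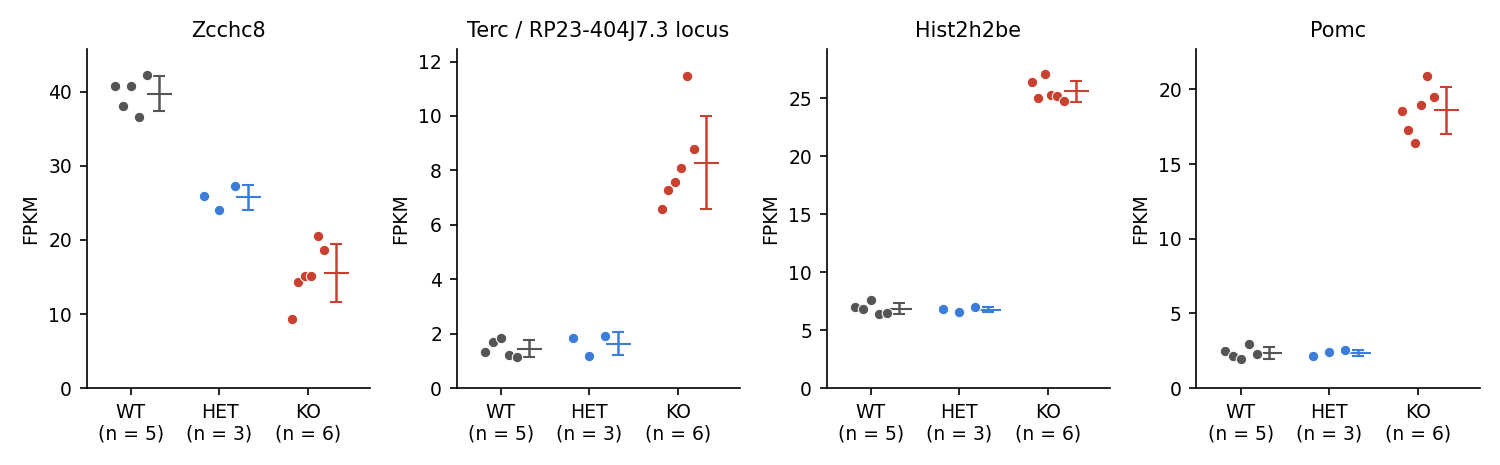
FPKM of 4 loci in every library by genotype (points) with the group mean and SD (bars), on linear axes that start at 0. Zcchc8 was lowest in KO, whereas the Terc locus, Hist2h2be and Pomc were higher in all 6 KO libraries than in any WT or HET library.

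KO heads gained RNA from many mostly low-abundance loci. Of 18217 loci, 3463 were higher and 1022 lower in KO than in WT, with a median log2 difference of 2.04 among the higher and -0.30 among the lower. Among changes of at least 2-fold, 2565 were higher and 45 lower. Unannotated loci made up a large part, with 1316 of 2004 higher and 9 lower. Protein-coding loci moved both ways, with 840 of 11880 higher and 881 lower. The number of loci at an FPKM of at least 0.1 was 24262 ± 988 (SD, n = 6) in KO and 20413 ± 178 (SD, n = 5) in WT (two-sided exact permutation p = 0.00216), and that of unannotated loci was 4379 ± 511 against 1831 ± 36.4. The count of lower calls over all loci depended on the libraries in the fit more than that of higher calls. It was 675 without WT4, 676 without KO4 and 1247 without KO5, where 3293, 3302 and 3458 loci were higher. With the replicate number as a block, 645 loci were lower and 3198 higher.

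The balance of higher and lower calls depended on how libraries were scaled. As deposited, 77.2% of the KO against WT calls were higher. With a common median, 3410 were higher and 1252 lower (73.1% higher). After quantile normalization the split was 2338 higher and 3801 lower (38.1%), and in the authors' quantile-normalized matrix, where the median of all loci shifted by 0.20 log2, it was 6969 higher and 269 lower (96.3%). Called the same way under all 4 scalings were 1754 loci higher and 138 lower, and these included 469 protein-coding loci higher and 121 lower. Without the authors' matrix, the other 3 scalings shared 2202 loci higher and 948 lower, with 504 and 816 of them protein-coding. Most lower calls were thus lost in the authors' matrix alone. Of unannotated loci, 536 were higher and 2 lower under all 4, where loci blank in the authors' matrix could not be called. Among genes named below, the calls of Cryba2, Actn2, Myl4, Perp, Klf4, Slc1a3, Nsg1, Npy, Ntrk2, Anapc5 and the loci of Aqp1 and Foxj1 were lost in the authors' matrix, and those of Usp18, Irf7 and Hemgn after quantile normalization, in each case without a change of direction. Rnu11, Rnu3b1, Rnu3b4, Gm26493, Gm23442, Mir652 and the loci of Gm24888 and Tmem39b had too many blanks to be tested in the authors' matrix, so their calls hold under the other scalings alone.

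**Figure D2:**
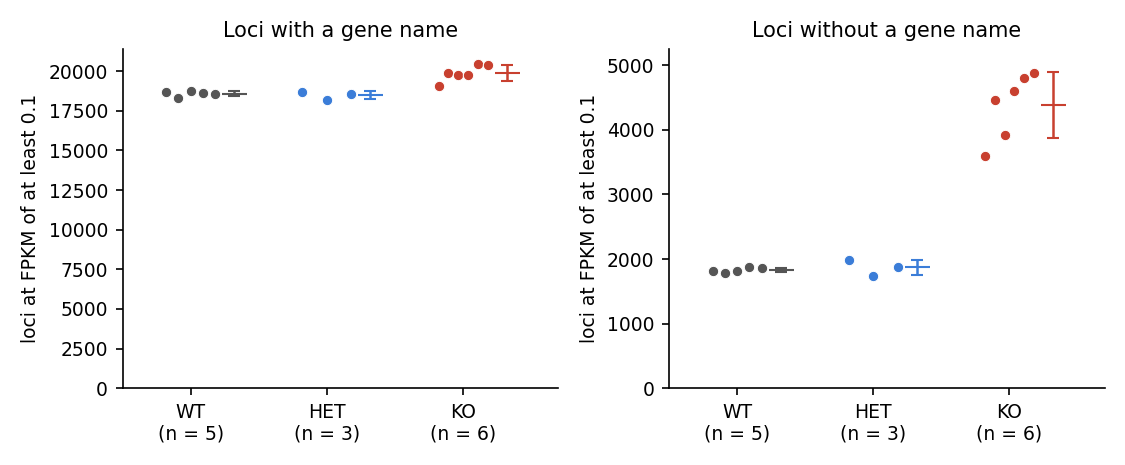
Number of loci at an FPKM of at least 0.1 in each library by genotype (points) with the group mean and SD (bars), for loci with a gene name (left) and without (right), on axes that start at 0. The KO libraries held 3602 to 4882 unannotated loci and the WT libraries 1789 to 1879.

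Calls by abundance were counted in quartiles. In the lowest quartile of mean FPKM, 2170 loci were higher and 87 lower, and in the highest quartile 123 were higher and 221 lower. Of single-exon genes 140 of 440 were higher, and of multi-exon genes 837 of 11618. As a class, single-exon genes rose relative to other loci by camera (p = 4.0e-04), but not with an estimated correlation (p = 0.209), without the filter (p = 0.238) or in the authors' matrix (p = 0.0940). Without the histone genes, 57 of 249 single-exon protein-coding genes were higher and 5 lower.

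**Figure D3:**
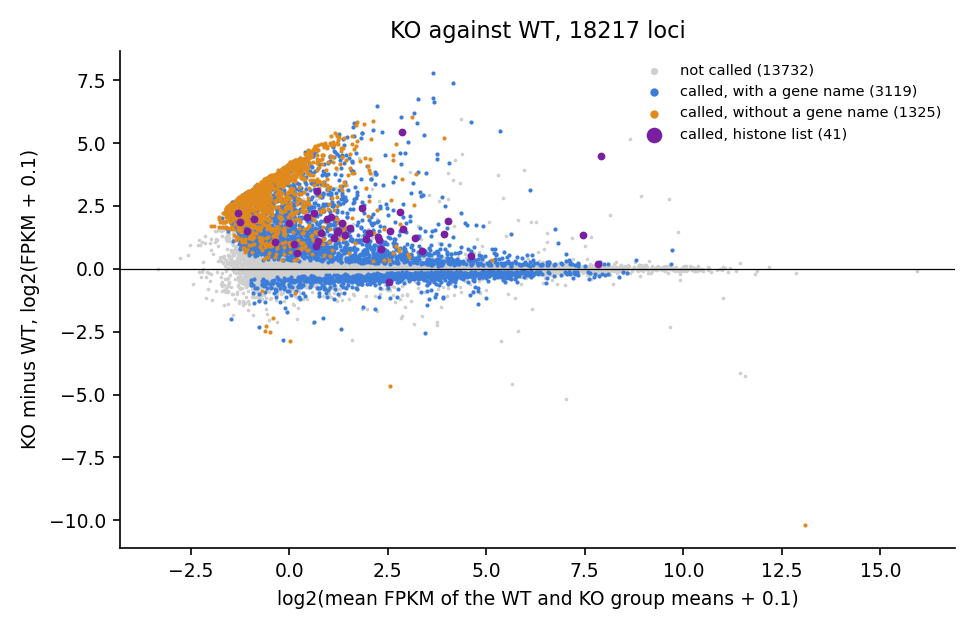
Difference between KO and WT in log2(FPKM + 0.1) of each tested locus against the log2 of its mean FPKM + 0.1, with called loci in color. Unannotated loci, in orange, lie mostly at low abundance and above 0, with 1316 higher and 9 lower.

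Many unannotated loci that rose lay just upstream of annotated genes. Of the 1316, 896 (68.1%) lay within 5 kb upstream of a gene start, against 248 of 688 other tested unannotated loci (36.0%, Fisher's exact p = 4.5e-43). They had a median length of 1518 bases and a median FPKM of 0.0307 in WT and 1.01 in KO, and 182 were listed at 0 in every WT library. Examples chosen after their values were seen include a locus on chromosome 15 (59647099 to 59648089), 261 bases upstream of Trib1, which rose from 0.308 ± 0.0434 (SD, n = 5) to 12.47 ± 1.5 FPKM (SD, n = 6). A locus on chromosome 8 (31168774 to 31169796), 10 bases upstream of Mak16, rose from 0.0147 to 4.42 FPKM, and 1 on chromosome 11 (75486266 to 75486642), 174 bases upstream of Prpf8, was listed at 0 in all WT libraries and had 4.25 ± 0.878 FPKM in KO (SD, n = 6). On chromosome 1 (134059946 to 134070072) a locus nearest to the start of Btg2, 9048 bases away on its downstream side, rose from 0.705 to 29.7 FPKM.

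The 12 largest rises were taken among called loci with a gene name and a mean of at least 1 FPKM in KO. Because polyadenylated RNA was selected, values of small nuclear, small nucleolar and telomerase RNA loci, here and below, cover polyadenylated RNA alone. The total level of these RNAs was not measured. Rnu11, a small nuclear RNA of the minor spliceosome, rose from 0.395 to 34.8 FPKM (log2 7.38). Its WT mean came from WT3 alone (1.97 FPKM), with the other WT libraries listed at 0. The U3 small nucleolar RNA gene Rnu3b1, for ribosomal RNA processing, rose from 0.129 to 14 FPKM (6.04, limma-trend adjusted p = 1.0e-09), and Rnu3b4 was listed at 0 in all WT libraries and had 9.11 ± 3.07 FPKM in KO (SD, n = 6). The clone-named RP23-480B19.12 rose from 0.0962 to 18.8 FPKM (6.75). A locus named Tmem39b, which is not the main locus of that gene, rose from 0.00921 to 6.00 FPKM (5.81). Others were Hist1h2bp (5.43), Mir7655 (5.43), Gm23444 (5.63), Gm23442 (5.80), the Gm24888 locus (5.82) and Gm22270 (5.50), while Gm26493 was listed at 0 in all WT libraries and had 24.7 ± 14 FPKM in KO (SD, n = 6). Gm23442 was at 14.4 FPKM in WT4 and listed at 0 in the other WT libraries, so its log2 rise is set by the libraries at 0. Without WT2 the adjusted p of the Gm24888 locus was 0.0502. For Gm22270 it was 0.103 without WT2, 0.0956 without WT5 and between 0.0566 and 0.0714 without any 1 of the KO libraries, KO3 and KO4 giving these ends. The rise of Gm22270 was 9.56 log2 among females and 2.71 among males (limma-trend adjusted p of the difference 0.0102).

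Replication-dependent histone genes, whose messages normally end in a stem-loop without a poly(A) tail, were tested as a list. Of 52 tested, 40 were higher and 1 lower, or 44 and 1 adjusted over the list alone, with a median of 1.29 log2. Camera gave an adjusted p of 4.3e-13, but 0.820 with an estimated correlation, and fry gave an adjusted p of 6.3e-06. The list, set by a name pattern, also holds the locus of H1f0, a replication-independent histone gene singled out after its values were seen, which is counted among the higher. Hist2h2be (chromosome 3, 96181151 to 96239127) rose from 6.86 ± 0.470 (SD, n = 5) to 25.6 ± 0.906 FPKM (SD, n = 6), a log2 change of 1.89 (SE 0.05). A locus shared by Hist1h4i, Hist1h4k, Hist1h4n and Prss16 rose from 20.2 to 460.1 FPKM, and the Hist2h2aa1 locus from 0.236 to 2.84. The median was positive under every scaling, at 1.28 with a common median, 0.89 after quantile normalization and 1.60 in the authors' matrix.

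Spliceosomal and other small nuclear RNA genes had 5 higher and 0 lower of 14, or 6 and 0 adjusted over the list alone (median 1.23). The camera adjusted p was 0.0484, but 0.820 with an estimated correlation, and the fry adjusted p was 1.6e-04. As fixed, this list also holds the U3 small nucleolar RNA genes, with Rnu3b1 and Rnu3b4, and other small RNA genes such as Rmrp and Rpph1. It is therefore not a list of spliceosomal RNA genes alone. Rnu1b6, a U1 gene, rose from 11.6 to 41.3 FPKM. The list's camera adjusted p was 0.0998 without WT1, 0.0717 without WT2, 0.0518 without KO1 and 0.0587 without KO4. It was 0.0581 without KO5, where the median was 0.81, and 0.969 in the authors' matrix, where the median was 0.73. The call was also lost with sex as a covariate and with loci spanning at least 300 bases.

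Small nucleolar and Cajal body RNA genes, which guide chemical modification of other RNAs, had 14 higher and 1 lower of 71 loci, of which 55 carry several names, often those of host genes such as ribosomal protein genes, and the same counts adjusted over the list alone (camera adjusted p = 0.591, but 0.00858 after quantile normalization and 0.0263 by fry). Snora16a rose from 14 ± 5.03 (SD, n = 5) to 124 ± 32.7 FPKM (SD, n = 6), and the locus of Snord17 and Snx5, which holds further names, from 74.0 to 154. Of 18 small nucleolar RNA host genes 4 were higher and 0 lower, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.884). Several names are carried by 15 of these loci. Snhg18, which shares its locus with Snord123, rose from 10.3 to 17.8 FPKM, and the Snhg3 locus, shared with Rcc1, from 58.0 to 83.8.

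Among telomerase and telomere maintenance genes 3 of 20 rose and 0 fell, with the same counts adjusted over the list alone (median 0.00095, mean 0.14, camera adjusted p = 0.907 in the direction of a fall, fry adjusted p = 0.0263 in that of a rise). Terc, the RNA template of telomerase, shares a locus with RP23-404J7.3 (chromosome 3, 96410692 to 96414913), which rose from 1.45 ± 0.305 (SD, n = 5) to 8.29 ± 1.72 FPKM (SD, n = 6), by 2.44 log2 (SE 0.16, limma-trend adjusted p = 1.1e-08). Nop10, a protein of box H/ACA particles, rose from 34.5 to 44.9 FPKM. Tinf2, a shelterin subunit, rose from 16.8 to 19.6 FPKM, with an adjusted p of 0.0579 without WT2. Of 24 nuclear exosome and cofactor genes 1 was higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.593). It was Srrt, with Mir7036 in the same locus, at 143 FPKM against 116 in WT.

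**Figure D4:**
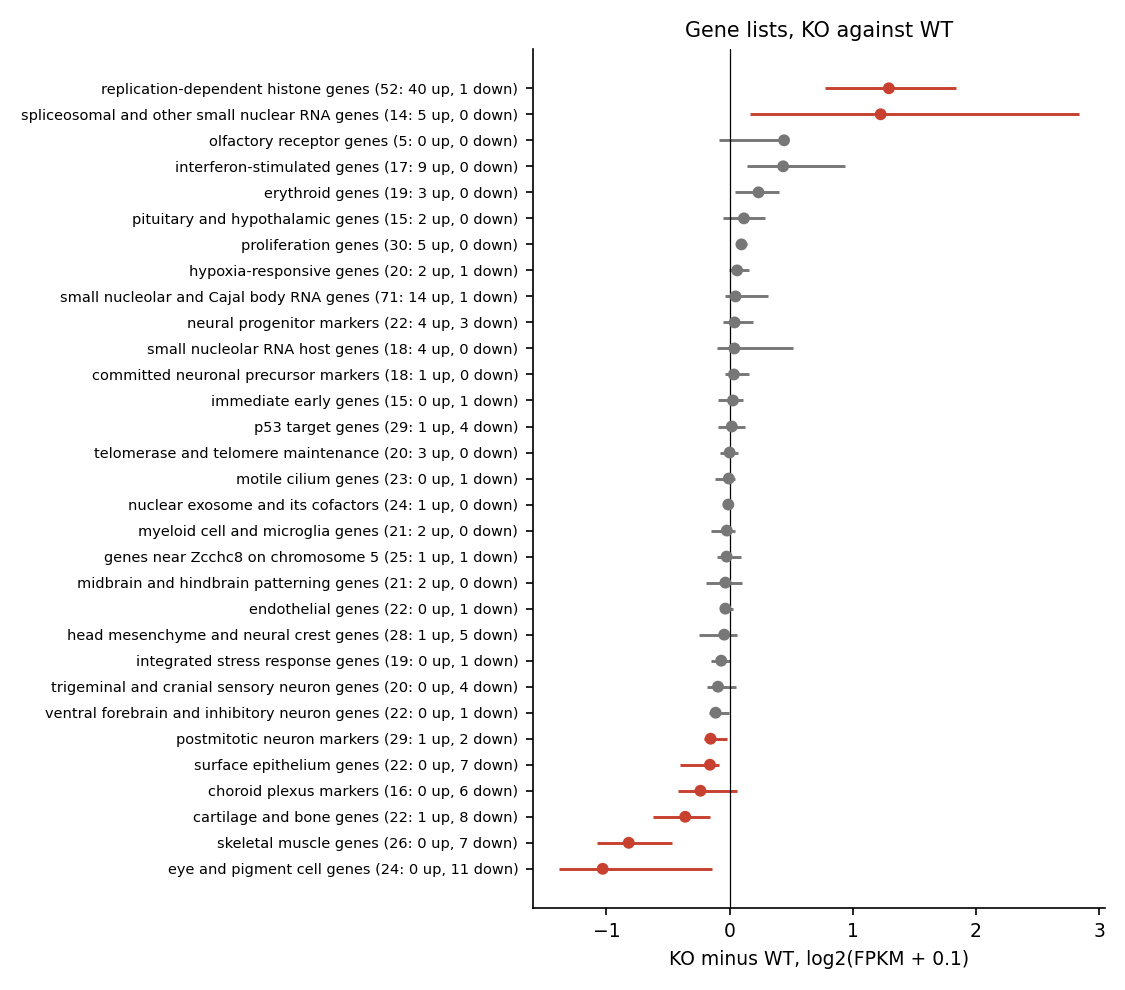
Median (points) and quartiles (bars) of the difference between KO and WT in log2(FPKM + 0.1) over the tested members of 31 lists fixed beforehand, the sex-linked list left out, with each list's size and called members. Lists past the threshold with the preset correlation are in red, and none of the 8 was past it with an estimated correlation; under the authors' matrix the medians of surface epithelium (0.22), choroid plexus (0.06) and neuron (0.03) lists among the 8 turned positive, against a shift of 0.20 of all loci.

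Of 24 eye and pigment cell genes 11 were lower and 0 higher, or 12 and 0 adjusted over the list alone (median -1.03). The camera adjusted p was 2.6e-04, but 0.820 with an estimated correlation, and the fry adjusted p was 0.0345. The called members were mainly crystallins, the structural proteins of the lens. Of 12 crystallins 10 were lower (median -1.40), and of 5 pigment cell genes 0 by limma-trend, with 0 also at an unadjusted p under 0.05 (median -0.07). The Cryga locus, shared with AC101869.3 and RP23-348D4.2, fell from 17.1 ± 3.92 (SD, n = 5) to 4.34 ± 5.05 FPKM (SD, n = 6), Crygd from 3.84 to 0.928, Crygb from 2.33 to 0.582, Cryba4 from 6.41 to 2.42 and Cryba2 from 5.04 to 2.07. KO libraries differed among themselves, with crystallin medians relative to WT of -1.22 in KO1, 0.02 in KO2, -1.93 in KO3, -2.34 in KO4, -0.81 in KO5 and -1.91 in KO6. The sexes were unequal, with 4 of the KO and 2 of the WT libraries female, and among female libraries alone the crystallin median was -1.29.

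Skeletal muscle genes had 7 of 26 lower and 0 higher, or 15 and 1 adjusted over the list alone (median -0.82, camera adjusted p = 6.5e-05, adjusted p = 0.820 with an estimated correlation and fry adjusted p = 0.152). Among female libraries alone the median was -0.65. The sarcomere gene Actn2 fell from 7.84 to 3.83 FPKM and the myosin light chain gene Myl4 from 20.1 to 9.66. The adjusted p of Actn2 was 0.0567 without WT2 and 0.0554 without WT4, and that of Myl4 was 0.0604 and 0.0599. Muscle medians per KO library were -1.53 in KO1, -2.11 in KO2, -0.49 in KO3, -0.80 in KO4, 0.15 in KO5 and -0.48 in KO6. Csrp3, a muscle LIM protein, fell from 1.32 to 0.394 FPKM.

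Cartilage and bone genes had 8 of 22 lower and 1 higher, or 10 and 1 adjusted over the list alone. Their median was -0.36, -0.32 among female libraries and -0.05 in the authors' matrix. Camera gave an adjusted p of 2.6e-04, but 0.820 with an estimated correlation, and fry gave an adjusted p of 0.0263. The cartilage matrix genes Matn4 and Col9a3 fell from 17.6 to 8.78 and from 33.1 to 17.7 FPKM, and the Matn1 locus, shared with RP23-218C2.2, from 2.71 to 0.719. Sox6, a transcription factor of chondrogenesis whose locus holds AC160535.2, rose from 7.88 to 11.6 FPKM. Of 28 head mesenchyme and neural crest genes 5 were lower and 1 higher, with the same counts adjusted over the list alone (camera adjusted p = 0.0798). Among them, Col1a2, a type I collagen chain, fell from 220.5 to 169 FPKM, the proteoglycan gene Dcn from 32.6 to 19.9, and the Foxc1 locus rose from 10.8 to 13.5.

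Surface epithelium genes had 7 of 22 lower and 0 higher, also adjusted over the list alone (median -0.16, and 0.22 in the authors' matrix). The camera adjusted p was 3.4e-04, but 0.820 with an estimated correlation and 0.0883 in the authors' matrix, and the fry adjusted p was 0.0263. Epithelium medians relative to WT were -0.04 in KO1, -0.26 in KO2, -0.15 in KO3, -0.19 in KO4, -0.25 in KO5 and 0.02 in KO6. WT libraries lay between -0.12 and 0.18, so KO1 and KO6 were within the WT range. The basal keratin gene Krt5 fell from 34.4 ± 5.51 (SD, n = 5) to 20.3 ± 2.58 FPKM (SD, n = 6), Krt14 from 22.9 to 14.2, Krt15 from 15.2 to 8.63 and Krt17 from 3.01 to 1.5. Choroid plexus markers had 6 of 16 lower and 0 higher, or 9 and 1 adjusted over the list alone (median -0.24, and 0.06 in the authors' matrix). Camera gave an adjusted p of 0.0248, but 0.820 with an estimated correlation, 0.121 after quantile normalization, 0.133 in the authors' matrix and 0.0629 among female libraries. Fry gave an adjusted p of 0.0263, and the camera call was also lost with the stricter filter and with single-name loci. Ttr, the thyroid hormone carrier transthyretin, fell from 108 to 75.1 FPKM, the potassium channel gene Kcnj13 from 0.986 to 0.609 and the water channel gene Aqp1, in a locus with Fam188b, from 13.9 to 10.3. Other large falls were Cpa3, a mast cell protease, from 1.10 to 0.387 FPKM, Pamr1 from 2.92 to 1.25 and RP23-410L16.8 from 1.21 to 0.439. Mir652 was listed at 0 in all KO libraries and had 1.58 ± 1.60 FPKM in WT (SD, n = 5). Its adjusted p rose to between 0.0629 and 0.108 without WT1, WT2, WT4 or any 1 of the KO libraries, KO5 and WT4 giving these ends.

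Postmitotic neuron markers had 2 of 29 lower and 1 higher, also adjusted over the list alone (median -0.15, and 0.03 in the authors' matrix; camera adjusted p = 0.0151, 0.0596 without WT3 with a median of -0.08, and adjusted p = 0.820 with an estimated correlation). The neuron list's camera adjusted p was 0.0423 in the authors' matrix, where the median of all loci shifted by 0.20 log2. It was 0.398 after quantile normalization, and fry gave an adjusted p of 0.307. The call was also lost with the stricter filter and with single-name loci. Nhlh2, a transcription factor of young neurons, rose from 30.9 to 45.5 FPKM, and Nsg1, a neuronal endosomal protein, fell from 164 to 140.0. Neural progenitor markers had 4 higher and 3 lower of 22, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.907), with Ccnd1 at 114 FPKM against 99.5 in WT and Slc1a3 at 17.6 against 21.7. Proliferation genes had 5 of 30 higher and 0 lower, but 0 and 0 adjusted over the list alone by limma-trend, where 10 had an unadjusted p under 0.05 (camera adjusted p = 0.347, and 0.00858 after quantile normalization). Of 18 committed neuronal precursor markers 1 was higher and 0 lower, or 0 adjusted over the list alone, where 2 had an unadjusted limma p under 0.05 (0.907), and of 22 ventral forebrain and inhibitory neuron genes 0 were higher and 1, Npy, fell from 7.05 to 4.08 FPKM (0.0643). Of 21 midbrain and hindbrain patterning genes 2 rose and 0 fell (0.749), Pax5 from 2.7 to 4.60 and En2 from 7.82 to 10.3 FPKM. Of 20 trigeminal and cranial sensory neuron genes 0 rose and 4 fell (0.0798), with Ntrk2 at 16.4 FPKM against 19.7 and Scn10a at 0.519 against 0.764, and of 23 motile cilium genes 0 rose and 1 fell, the locus of Foxj1 and Rnf157 (0.244, and 9.8e-04 after quantile normalization). The ventral forebrain list's adjusted p was 0.0370 without WT2, 0.0314 without WT5, 0.0338 without KO2 and 0.0453 without KO6, and the trigeminal list's was 0.0209 without KO1. Their medians of -0.11 and -0.09 turned to 0.04 and 0.03 among female libraries (adjusted p = 0.982 and 0.897) and to 0.17 and 0.27 in the authors' matrix (0.338 and 0.370), and after quantile normalization the adjusted p was 0.447 and 0.233. For the last 4 lists the counts were the same adjusted over the list alone, and the values in parentheses are camera adjusted p.

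Among stress and blood lists, interferon-stimulated genes had 9 of 17 higher and 0 lower, or 11 and 0 adjusted over the list alone (median 0.44). The camera adjusted p was 0.0587, 0.0029 among named loci, 0.0345 by fry, and adjusted p = 0.820 with an estimated correlation. It was 0.0419 without WT1, 0.0394 without WT5, 0.0393 without HET3, 0.0496 without HET5, 0.0358 without KO1, 0.0493 without KO4 and 0.0483 without KO5. It was 0.356 after quantile normalization (median 0.19), 0.764 in the authors' matrix (median 0.78) and 0.310 among female libraries. The locus of Rtp4 and RP23-389N20.2 rose from 1.74 to 3.61 FPKM, Usp18, a negative regulator of interferon signalling, from 0.479 to 1.23 and Irf7, a transcription factor of the response, from 0.624 to 1.32. Of 29 p53 target genes 1 was higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.593), with the Tnfrsf10b locus, shared with 4930480K23Rik, at 7.03 FPKM against 4.86 and Perp at 7.57 against 10.2. Erythroid genes had 3 of 19 higher and 0 lower, also adjusted over the list alone (0.501), with Hemgn up from 0.397 to 1.25 FPKM. Hypoxia-responsive genes had 2 higher and 1 lower of 20, also adjusted over the list alone (0.907). Of 19 integrated stress response genes 0 were higher and 1 lower, or 0 and 0 adjusted over the list alone, where 2 had an unadjusted limma p under 0.05 (0.101). Of 15 immediate early genes 0 were higher and 1 lower, also adjusted over the list alone (0.593); it was Klf4, at 7.11 FPKM against 9.34.

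Of 15 pituitary and hypothalamic genes 2 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.639, fry adjusted p = 9.96e-04; median 0.12, and -0.27 after quantile normalization). Pomc, the precursor of adrenocorticotropin and melanocortins (chromosome 12, 3954951 to 3960848), rose from 2.36 ± 0.397 (SD, n = 5) to 18.6 ± 1.59 FPKM (SD, n = 6), by 2.94 log2 (SE 0.10, limma-trend adjusted p = 1.5e-11). Of 22 endothelial genes 0 were higher and 1 lower, also adjusted over the list alone (0.279), and of 21 myeloid cell and microglia genes 2 were higher and 0 lower, or 0 and 0 adjusted over the list alone, where 3 had an unadjusted limma p under 0.05 (0.323). Of 25 genes near Zcchc8 on chromosome 5, 1 was higher and 1 lower, also adjusted over the list alone (0.501), the Setd1b locus at 29.7 FPKM against 19.1 and Anapc5 at 185 against 209. Among 5 olfactory receptor genes, which are silent in most of the head, and among 6 X inactivation and Y-linked genes 0 were called by limma-trend, also adjusted over the list alone (0.907 and 0.501), with 1 and 0 at an unadjusted p under 0.05. The 5 were those of 1399 olfactory receptor loci that passed the filter. Of them 3 carry several names, so their values may come from other genes. For the p53 target, immediate early, neural progenitor, committed precursor and olfactory receptor lists the median and the mean lay above 0 while camera's direction was a fall relative to other loci.

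HET and WT heads were compared locus by locus and by list. By limma-trend 1 of 18217 loci passed the threshold and 354 had an unadjusted p under 0.05. It was an unannotated locus on chromosome 17 (79554051 to 79554268), named after its values were seen, listed at 0 in all WT and KO libraries and at 1.05 ± 0.811 FPKM in HET (SD, n = 3), and the count was 0 without HET3 and 2 without WT1, WT3 or KO1. Pomc was at 2.37 ± 0.20 FPKM in HET, Hist2h2be at 6.76 ± 0.223 and the Terc locus at 1.64 ± 0.409 (SD, n = 3). HET libraries held 20339 ± 370 loci at an FPKM of at least 0.1 (SD, n = 3; two-sided exact permutation p = 0.75) and 1870 ± 120 unannotated loci.

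With the preset correlation, 5 lists passed the threshold in HET against WT. Immediate early genes (camera adjusted p = 9.3e-04), nuclear exosome and cofactor genes (0.0333) and small nucleolar RNA host genes (0.0405) were lower, and committed neuronal precursor markers (0.0181) and eye and pigment cell genes (0.0261) higher. None passed with an estimated correlation or by fry, and by limma-trend 0 members were called, with 1, 2, 0, 0 and 0 of these lists in turn at an unadjusted p under 0.05. The number of lists was 10 without WT3, 2 without WT4 or WT5 and 1 without HET4.

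Of the 4485 loci called in KO, 51.5% lay on the same side of WT in HET, against 50.1% (48.7% to 51.6%) in simulations with no HET effect that shared the WT libraries. With WT split into 3 and 2 libraries the share averaged 51.4% (46.1% to 57.6%). The covariance of the log2 differences was 0.0708, against 0.0456 simulated with no HET effect, a difference of 0.0251.

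The histone, neuron, choroid plexus, muscle, cartilage, surface epithelium and eye lists passed the threshold by camera in KO against HET as in KO against WT, and the ventral forebrain list in KO against HET alone (adjusted p = 0.0193). The small nuclear RNA list passed in KO against WT alone (0.0717 in KO against HET), and differences between the comparisons were not tested. None of these lists passed with an estimated correlation (adjusted p = 0.731 for each). Of 18217 loci, 3265 were higher and 794 lower in KO. The split was 3164 and 1142 with a common median, 2092 and 3256 after quantile normalization and 4619 and 217 in the authors' matrix. Without 1 library the lower calls ranged from 267 (without HET3) to 932 (without KO5). The higher calls ranged from 2837 (without HET4) to 3398 (without KO1). The largest rises among named loci were Rnu11 (7.19 log2), Rnu3b1 (6.73), the Gm24888 locus (6.6), RP23-480B19.12 (6.47) and Rnu3b4 (5.95). The largest falls were the Cryga locus (-2.78), Crygd (-2.74), Crygb (-2.21), Cryba4 (-2.01) and Csrp3 (-1.83). Zcchc8 differed by -0.77 (SE 0.17, limma-trend adjusted p = 0.0038; two-sided exact permutation p = 0.0119). The smallest camera adjusted p of the 8 lists were those of the histone genes (40 of 52 higher, adjusted p = 1.9e-12) and the eye and pigment cell genes (12 of 24 lower, 1.4e-05), both at adjusted p = 0.731 with an estimated correlation.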

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

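The tests of sequencing depth, of carried-over RNA, of an interaction with sex and of sex for lens genes alone were chosen after the results were seen. Of 255 groups of 4 to 10 libraries, 21 had a library far from the others, and chance alone gives about 12.8.

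In these groups 1 library lay apart. Among WT libraries, Rnu11 was at 1.97 FPKM in WT3 and listed at 0 in the others, the Tmem39b locus at 0.0461 in WT4 and 0 in the others, and Gm23442 at 14.4 in WT4 and 0 in the others. Snora16a was at 22.7 FPKM in WT5, Kcnj13 at 0.810 in WT3 and Krt15 at 19.1 in WT4. The locus of Olfr456 and Tcaf2 was at 1.45 FPKM in WT2, with the other WT libraries at 0, and at 2.36 in KO2. Among KO libraries, KO2 stood above the others for the Cryga locus (14.2 FPKM), Crygb (1.69), Vldlr (6.47), Btg2 (29.6) and Nsg1 (159). KO5 stood above the others for the Gm24888 locus (127 FPKM), the Matn1 locus (2.19), Npy (5.93) and Matn4 (14.6). Usp18 was highest in KO6 (1.81 FPKM) and Dll3 lowest in KO3 (10.5 FPKM). The neuron marker median was 0.14 in KO2, against -0.23 to -0.11 in the other KO libraries. Y-linked RNA reached 2.47% of the male mean in the female library HET4, against at most 0.128% in the other female libraries.

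KO minus WT differed between male and female libraries at 103 loci by limma-trend with Benjamini-Hochberg adjustment. The lowest adjusted p was 0.0063, and 3329 loci had an unadjusted p under 0.05. At most of the 103 loci, KO minus WT was lower in males than in females. The groups were small, with 2 male and 4 female KO and 3 male and 2 female WT libraries. The male KO libraries were KO2 and KO3, so sex cannot be told apart from other traits of these 2 libraries. Gm22270 rose by 9.56 log2 in females and 2.71 in males, a difference of -6.85 (adjusted p = 0.0102).

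The first pattern was the rise of 1316 unannotated loci in KO. Risen loci lay within 5 kb upstream of a gene start more often than other unannotated loci (odds ratio 3.78), so stabilised transcription upstream of genes may be one source. The values argue against depth as the whole cause, since HET libraries of about the same relative depth as KO (medians 1.30 and 1.31) detected fewer unannotated loci than every KO library, the lowest KO library being at 1.82 times the highest HET library. A bound set before, that the value of 1 fragment would differ by under 10% between KO and WT, was not met, since it was 12.3% lower in KO. The values also argue against genomic DNA, since the median rise over 1356 olfactory receptor genes was 0% of that over the risen loci.

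For the second pattern, the fall of lens, muscle and cartilage genes, a dissection that left out eyes would lower pigment cell genes as well. Their median lay 1.32 log2 above that of the crystallins, more than their own range of 0.59. By library, pigment medians were 0.22 in KO1, 0.15 in KO2 and 0.03 in KO3, but -0.16 in KO4, -0.56 in KO5 and -0.30 in KO6. KO4, KO5 and KO6 lay below every WT library (-0.14 to 0.11). The crystallins also fell in KO1 and KO3, where pigment genes did not. For KO4, KO5 and KO6 a part played by dissection cannot be excluded. Unequal numbers of males and females do not account for the lens genes, since the highest female KO library differed by -0.40 log2 from the lowest female WT library. Among female libraries alone, where the sexes cannot differ, the highest of the 3 medians was -0.32, for cartilage, and that of muscle was -0.65. Both lists were past the threshold there by camera with the preset correlation (adjusted p = 0.0036 and 1.97e-04). The female KO and WT libraries overlapped, however. KO5 had muscle and cartilage medians of 0.15 and -0.02, above the -0.11 and -0.13 of WT5, a condition applied after the values were seen. The fall of muscle and cartilage genes among females was thus not beyond the spread of single libraries, and no conclusion on sex was drawn for them. A shift to an earlier neuronal stage can be neither excluded nor shown, as the neuron markers had a median of -0.15, between the bounds of -0.1 and -0.2. A slower development of these tissues in KO heads was not tested.

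The third pattern was the 39.1% of Zcchc8 RNA left in KO libraries. WT RNA carried over from the other sex would bring its sex-linked RNA, yet that reached at most 0.120% of its level in a KO library. Carry-over from a WT head of the same sex would leave no such RNA, so the values cannot exclude it. Transcripts from the altered allele remain a possible explanation that was not tested.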

How the results depend on the processing

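The authors' matrix, single-name loci, female libraries and the 300-base minimum were chosen after seeing the data, and where no cause is given it was not tested. Count-based tests were not run because the files hold no counts. KO against WT calls numbered 2657 with FPKM of at least 1 in at least 5 libraries, 2093 with single-name loci (both test fewer loci), 2610 at an absolute log2 change of at least 1 and 7238 with the authors' matrix, and 3956 to 4854 without 1 library. For KO against HET these were 2430, 1823 and 2547, and 3162 to 4294 without 1 library. HET against WT gave 0 by limma-trend with pseudocounts of 0.5 and 1, FPKM of at least 1, single-name loci, spans of at least 300 bases and without HET3, against 354 at an unadjusted p under 0.05 in the fit as reported. It gave 2 with no filter, quantile normalization, library weights, female libraries or without WT1, WT3 or KO1, and 3 with only the 2 groups in the fit, where Zcchc8 in HET was at -0.62 (adjusted p = 0.0177).

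The number of lists past the threshold in KO against WT, 8 as reported, was 13 with no filter, 5 in the authors' matrix, 0 with an estimated correlation and 7 to 10 without 1 library. For HET against WT, 5 as reported, it was 3 with no filter, a common median, single-name loci or female libraries, 0 with an estimated correlation or fry, and 1 to 10 without 1 library. In the fit as reported the median log2 difference was 0.22 for single-exon and -0.04 for multi-exon genes, a gap of 0.25. This gap moved to 0.092 with no filter (camera p = 0.238) and 0.22 in the authors' matrix (p = 0.0940). It stayed at 0.25 with an estimated correlation (p = 0.209). The gap was 0.11 after quantile normalization and 0.42 among female libraries, with single-exon genes past the threshold by camera in both.

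The labels do not say whether equal replicate numbers mark a shared litter or batch. Same-numbered libraries had correlations of -0.11 to 0.10, and not every library correlated best with its own number. These values gave no clear pairing but cannot exclude one. With a replicate block, KO against WT had 3843 calls, KO against HET 3404, HET against WT 0, and 9 and 8 lists passed, against 8 and 5.

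In the authors' matrix the sign reversed for the Zfp28 locus with Olfr1344 (0.34), Vldlr (0.17), Ndrg1 (0.038), Clic6 (0.16), Alpl (0.020) and Erg (0.021). The median of all loci shifted by 0.20 log2 there, and all of these but the Zfp28 locus lay below that shift. After quantile normalization the sign reversed for Car9 (-0.043), Ptf1a (-0.77) and the Tekt4 locus (-0.76). The telomere list reversed by fry (median 0.00095, fry adjusted p of 0.0263). Otherwise named genes kept direction and side of the threshold 2993 times, lost the call 208 times and gained one 50 times, and lists 927, 28 and 34 times. Counted as kept are 57 sign changes of values past the threshold in neither setting. Zcchc8 in KO stayed between -1.48 and -1.25 without 1 library.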

Other observations

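The tests of sex-linked RNA and depth given above were chosen after the results were seen, and the comparisons with other splits of the libraries were planned. Loci named after clones of the genome project (RP23 and RP24) and non-coding RNA loci also shifted upward. Of 1788 clone-named loci 823 were higher and 21 lower in KO than in WT, and of 182 non-coding RNA loci 91 were higher and 2 lower, by limma-trend. A locus on chromosome 4 (136132852 to 136136355), chosen after its values were seen and 7142 bases upstream of Id3, went from 0.0515 ± 0.0202 (SD, n = 5) to 5.81 ± 0.746 FPKM (SD, n = 6).

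The lens and muscle medians did not move together in every KO library. In KO2 the crystallin median was 0.02 and the muscle median -2.11, while in KO5 they were -0.81 and 0.15. An unannotated locus of 100 bases had 1124050 FPKM in HET4 and 0 in the other libraries, and it did not pass the filter on low values.

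Other divisions of the same libraries into groups of the same sizes were used to see whether chance could be excluded. For KO against WT genes it could, with 1 of 100 divisions (the real one, 4485 calls) and 3753 in the highest other, which moved only KO3 to the WT side. For KO against HET it could, with 1 of 84 (4059 calls, highest other 5). It could not for HET against WT genes (21 of 56, real 1, highest other 3), for lists in KO against WT (56 of 100, real 8, highest other 14), for lists in HET against WT (43 of 56, real 5, highest other 15) or for single-exon genes (25 of 100, real statistic 3.40, highest other -7.67 by size).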
